A study of Oncorhynchus mykiss with 9 samples.

How the data were processed

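Head kidney RNA of rainbow trout was measured in 9 libraries, 3 per group, and the groups were taken from the treatment given in the labels. The fish were full siblings, per the labels. The deposited table holds, per gene, 1 FPKM value and 1 estimated count per group and no value per library, per the file headers. HISAT2 and Bowtie2 2.2.8 are named in the submitters' processing notes with no role. The counting tool, genome build and filters are not given in the sources used here. The deposited counts are taken as means of 3 libraries because, after multiplication by 3, 73.9% of the non-zero values in the control, 69.6% in moderate and 71.5% in severe hypoxia were whole within 0.002; the rest are estimated counts. The FPKM values were computed by the authors and are fragments scaled by gene length and library size, per the file headers.

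The table is printed in 16 fields of 8 characters and was read by position. It holds 44219 genes, 2322 of them loci assembled by the authors, and 1985 further lines of text that ran over from descriptions. IDs, symbols and descriptions end after 8 characters, so that IDs take only 95 distinct values and copies of a gene were told apart only by row. A symbol was present for 37624 genes, and 2758 of them had symbols of exactly 8 characters. Those were used for a list only where each symbol of the RefSeq gene table of assembly USDA_OmykA_1.1 that starts that way belonged to the list. The symbols are the authors' assignments. Rows of near-identical copies share reads, and 72 analysed rows shared all 6 values with another row, so single copies are uncertain.

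The planned analysis, a quasi-likelihood test on 9 libraries with competitive tests of gene lists and tests of enrichment, could not be run, since the file holds 1 value per group. Groups were compared as values instead. The 28711 genes with a mean of at least 10 counts per library in a group were analysed. Counts were scaled by the trimmed mean of M values (30% of ratios and 5% of abundances trimmed), computed with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15, with figures drawn in matplotlib 3.10.9. Moderate and severe counts were divided by 1.62 and 1.22 relative to the control. A gene was counted at 2-fold or more. Where a group was at 0, the fold was set against 3 counts over that group and is a lower bound. Counting intervals are exact Clopper-Pearson 95% intervals for the counts of both groups summed over 3 libraries; they leave out variation between fish, which is unknown. Reads carried no molecular identifiers, so they cover counting error only.

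Before the data were examined, 18 pathway lists and 11 lists of cell type markers were fixed. Family entries known by product name alone were not matched. A list's median log2 ratio was set against 10000 random lists drawn from 20 bins of abundance, leaving out its own members, and named when below percentile 2.5 or above 97.5, which is a description and not a test. In a second version, chosen after seeing the data, each member was replaced by 1 of the 40 genes nearest in abundance and length, length being derived from the deposited count and FPKM for 28177 genes (median 2708 bases). For ribosomal proteins, other rows described as ribosomal were kept out of the draws. First-listed KEGG pathways of 10 or more genes were treated in the same way. The genes named were, per comparison with the control, the 8 largest ratios in each direction with at least 50 counts in the higher group and a symbol, 5 for severe against moderate, up to 3 members per list, and hif1a, egln3, vegfa, epo, hbb and star throughout. The rule's demands on an adjusted p and on separate replicates could not be applied, and members were taken by the size of the ratio. The text gives a selection of the genes so named.

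The scaling and the percentiles were tested on simulated counts of 25959 genes, with counting noise only. For moderate against control, the median log2 ratio of unchanged genes was -0.001, 100% of 4-fold changes were found, and 1.0% of 1.5-fold changes were counted. For severe against control, 7 of 100 unchanged lists fell outside the central 95%, and 100 lists shifted by 0.5 were found. These lists were random genes, and the simulation held no trend with gene length and no copies that vary together. On library totals its unchanged genes stood at 0.129 for moderate against control, while the median of all genes in the data was 0.693. It thus checks the computation and not how the scaling or the percentiles behave in these data. Alternatives were library totals, median-of-ratios size factors, other minimum counts and folds, FPKM with pseudocounts of 1 and 0.1, totals without globin and mitochondrial genes, and removal of the trend with gene length in 50 bins.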

Results

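RNA was sequenced from the head kidney of rainbow trout (Oncorhynchus mykiss) of about 130 g kept at 12 °C. The head kidney is the main blood-forming organ of bony fishes and also holds the interrenal and chromaffin cells, which make cortisol and catecholamines. There were 9 libraries in 3 groups of 3: normoxic controls at 8.5 mg/L dissolved oxygen, labelled 0 h, moderate hypoxia at 4.5 mg/L for 12 h, and severe hypoxia at 3.0 mg/L for 12 h. The comparisons ask how the organ's transcripts differ at each oxygen level. The deposited values are 1 mean estimated count and 1 FPKM per gene and group, so the spread between fish is unknown, no difference below has a replicate check, and no p-value is given for any of them. Both hypoxia groups differ from the control in sampling time as well as in oxygen, while the labels of the severe and moderate groups differ in oxygen and not in time.

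The mean total per library was 15246482 counts in the control, 15301518 in moderate hypoxia and 14700244 in severe hypoxia. Globin transcripts, the product of red blood cells, took between 12.99% and 13.01% of counts in the control (Wilson 95% interval), 4.12% in moderate hypoxia (4.11 to 4.12) and 7.37% in severe hypoxia (7.37 to 7.38). Mitochondrially encoded transcripts took 5.14%, 2.36% and 4.24% in the same order. The 100 most abundant genes held 38.3%, 23.0% and 31.3% of the counts. Intervals cover counting error only. Counts below are the deposited group means per library. Ratios follow scaling by the trimmed mean of M values, which divided moderate counts by 1.62 and severe counts by 1.22 relative to the control. On library totals alone, the median of all genes stood 0.69 above 0 on the log2 scale for moderate against control, 0.34 above 0 for severe against control and at -0.34 for severe against moderate. Percentiles of gene lists, given against 10000 random lists of equally abundant genes, do not depend on that choice.

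In moderate hypoxia, genes of DNA replication and mitosis, of the endoplasmic reticulum stress response and of T and NK cells were higher than in the control. Transcripts of red blood cells, of complement, and of muscle and liver were lower. Those of the interferon response were lower on scaled counts. On library totals and on the FPKM scales their median was near 0, still below that of equally abundant genes (percentile 0.00). Those of oxidative phosphorylation were lower to a degree that depended on scaling and gene length. The cortisol-responsive gene fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, was 8.42-fold higher in 1 of its 2 copies (counting interval 7.50 to 9.49), with mean counts of 102 and 1385, and 3.27-fold higher in the other. The HIF target egln3, a prolyl hydroxylase that marks HIF for degradation, was 2.74-fold and 2.07-fold higher in its 2 copies. As lists, glucocorticoid response genes (median -0.04, percentile 46.9) and HIF targets (median -0.01, percentile 62.1) did not differ from equally abundant genes.

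The list of DNA replication and mitosis had a median log2 ratio of 0.57 (percentile 100), with 10 of 58 members at least 2-fold higher and 0 lower. The share at least 2-fold higher was below that of all genes (5734 of 28711), so the count of higher members does not mark the list. Above 0 were 52 of the 58 members. Examples were the helicase subunit mcm3, with counts of 436 and 1883, top2a (1045 and 4396), and a rrm1 row (79.0 and 532; log2 ratio 0.78 over both rows). The endoplasmic reticulum stress and amino acid list had a median of 0.39 (percentile 100), with 18 of 60 members at least 2-fold higher and 3 lower. Its largest ratios were those of single rows of the chaperone cofactor dnajb11 (5.88-fold) and asparagine synthetase asns (5.35-fold), and of eif2ak3, the kinase PERK (4.58-fold). Over both rows of each symbol, dnajb11 was at a log2 ratio of 1.73 and asns at 2.22. Of the T and NK cell markers, 10 of 36 were at least 2-fold higher and 1 lower, with a median of 0.56 (percentile 99.5), and a prf1 copy encoding perforin was 4.07-fold higher. B cell markers had a median of 0.31 (percentile 97.7). The 59 members of that list are rows of 13 symbols, each row entering as a separate member. The symbol CD22 is carried by 43 rows, whose descriptions differ, and all of them together were at a log2 ratio of 0.09. The inflammatory list had a median of 0.29 (percentile 98.7), with tlr1 4.46-fold higher, and it lay at percentile 85.5 after the trend with gene length was removed. A mmp9 copy, encoding a neutrophil gelatinase, was at 5197 and 37705 counts, although the neutrophil markers as a list had a median of -0.01 (percentile 94.6, and 98.2 with length matching).

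Of the 34 erythroid markers, 20 were at least 2-fold lower and 3 higher, with a median of -1.11 (percentile 0.00). The most abundant hbb row was at 195906 and 76753 counts, a log2 ratio of -2.05, and an abundant hba row was at -2.73. The oxidative phosphorylation list had a median of -0.92 (percentile 0.00; 0.53 among lists matched on abundance and gene length), with 87 of 195 members at least 2-fold lower and 6 higher, and sdhb at -2.41 in 1 row and -0.73 over its 3. The list had a median of -0.06, at percentile 88.6, after the trend with gene length was removed. Interferon response genes had a median of -0.74 (percentile 0.00), with ifit9 at -1.63 and ifit10 at -1.69. On library totals their median was -0.05, and on the FPKM scale with a pseudocount of 1 it was 0.02, both also at percentile 0.00. Complement and acute phase genes had a median of -1.10 (percentile 0.00), with 18 of 35 at least 2-fold lower. Muscle markers had a median of -3.22 and those of liver and exocrine pancreas -3.46, both at percentile 0.00. The apolipoprotein apoa2 was at 229 and 5.33 counts, and fibrinogen chain fga at 64.7 and 3.00.

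Cytosolic ribosomal proteins had a median of -1.51 and 149 of 163 members at least 2-fold lower. Their percentile was 0.00 among equally abundant genes and 90.9 among genes of like abundance and length, while with the trend with gene length removed it was 0.26 at a median of -0.42. The antioxidant list (median -0.74) had percentiles of 0.00 and 3.78 in that order, and catalase, cat, was at -2.25 in 1 row and -1.22 over its 3. Lists of autophagy (median -0.31) and chromaffin cells (median -0.66) had percentiles of 3.41 and 3.96, and of 0.32 and 0.29 with length matching. On library totals their medians were above 0, at 0.38 and 0.03.

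HIF targets had a median of -0.01 (percentile 62.1), with 13 of 64 members at least 2-fold higher and 11 lower. Glycolysis (median -0.11, percentile 64.0) included gapdh and ldha copies at -4.18 and -3.98, while all rows of each symbol together were at -0.23 and -3.44. The lists of chaperones (median -0.15), apoptosis (-0.30), antigen presentation (-0.20), steroid synthesis (-0.24), glucocorticoid response (-0.04), circadian clock (0.25) and lipid storage (0.25) lay inside the central 95% of random lists. So did the markers of thrombocytes (0.03), macrophages (0.01), endothelium (0.14) and kidney tubule (0.14). On library totals the medians of HIF targets, glycolysis, chaperones, apoptosis, antigen presentation, steroid synthesis, glucocorticoid response and neutrophils were above 0. Within the glucocorticoid list, a sgk1 copy was 7.63-fold higher (log2 ratio 1.10 over its 5 rows) and pdk4 6.09-fold higher. The hif1a copies had log2 ratios of 0.59, 0.03, 1.13 and -0.20, and the more abundant vegfaa row, VEGFA and vegfab were at -0.81, -0.55 and 0.27, with VEGFA at 0.14 on library totals. The 3 epo rows were at 4.00 counts or fewer in every group. The star gene, whose product carries cholesterol into mitochondria for steroid synthesis, was at 2405 and 1875 counts, a log2 ratio of -1.05.

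Among single genes, EIF3B was at 0 counts in the control and 378 in moderate hypoxia, at least 233-fold higher. It was at 0 counts in severe hypoxia as well. Only 1 row carries the symbol, so reads assigned to a copy under another symbol cannot be told apart from a change. The immunoglobulin segment IGHV3-48 was at least 166-fold higher, with 268 counts in moderate hypoxia. A fth1-a row, encoding ferritin heavy chain, was at 1511 and 0 counts, at least 2450-fold lower, while the 13 rows of that symbol together had a log2 ratio of -2.17. The type X collagen gene COL10A1 was at 89.0 and 0.333 counts (log2 ratio -8.76, counting interval -14.06 to -6.27), with -7.14 over its 3 rows. Other large ratios belonged to 1 row of a symbol whose rows together differed little: ARPC1B was 213-fold higher in 1 row and at -0.67 over both, and prmt5 was at -7.81 in 1 row and at -0.11 over its 3. Of 28711 genes, 5734 were at least 2-fold higher and 4043 lower, so 58.6% were higher. On library totals the split was 10899 and 1354, or 88.9% higher.

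**Figure D1:**
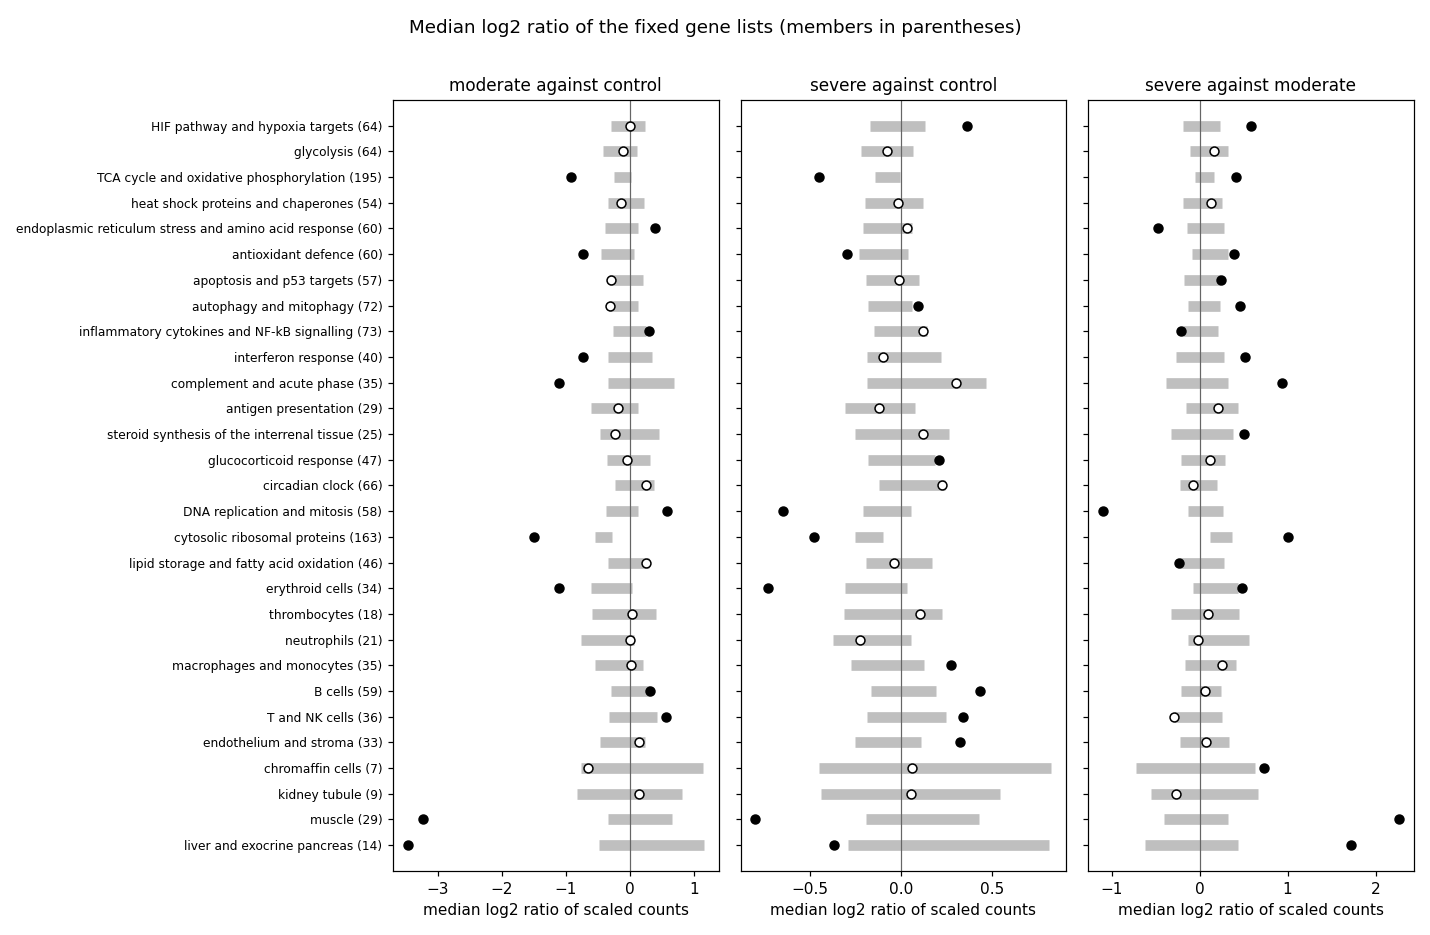
Median log2 ratio of scaled counts (x axes) for the 29 gene lists (rows, members in parentheses) in the 3 comparisons. Filled points lie outside the central 95% of 10000 random lists of equally abundant genes, drawn as a grey bar, and open points lie inside it. DNA replication stands at 0.57, -0.65 and -1.10 from left to right.

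In severe hypoxia, HIF targets and markers of macrophages, T and NK cells and endothelium were higher than in the control. So was the B cell list, whose 59 members are rows of 13 symbols, many of them CD22 rows with differing descriptions. DNA replication genes, oxidative phosphorylation genes, red blood cell markers and muscle markers were lower. The stress gene ddit4, a HIF target that inhibits mTORC1, was at 0.333 counts in the control and 89.0 in severe hypoxia, a log2 ratio of 7.78 (counting interval 5.28 to 13.08), with 1.31 over its 3 rows. The egln3 copies were 11.4-fold (counting interval 9.27 to 14.2) and 6.66-fold higher. The FKBP5 copies were 8.43-fold and 3.58-fold higher.

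The HIF list had a median log2 ratio of 0.37 (percentile 100), with 15 of 64 members at least 2-fold higher and 2 lower. A copy of P4HA1, a collagen prolyl hydroxylase, was 9.00-fold higher, while its 4 rows together were at 0.12. Of the vegfa copies, vegfab was at a log2 ratio of 0.75, the more abundant vegfaa row at 0.11 and VEGFA at 0.04. Autophagy genes had a median of 0.10 (percentile 99.5), with 41 of 72 members above 0, 5 at least 2-fold higher and 1 lower: a WIPI1 copy was 2.84-fold higher and a WIPI2 copy 2.34-fold lower. The share at least 2-fold higher was below that of all genes (3934 of 28711). Macrophage markers had a median of 0.27 (percentile 99.97), with a MRC1 copy, the mannose receptor, 3.11-fold higher. B cell markers, among them the repeated CD22 rows, stood at 0.43 (percentile 100). T and NK cell markers stood at 0.34 (percentile 99.5) and endothelium at 0.32 (percentile 99.99). The endothelial gene EGFL7 was 3.35-fold and cxcl12a 3.99-fold higher in 1 row each.

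DNA replication genes had a median of -0.65 (percentile 0.00), with 10 of 58 members at least 2-fold lower and 2 higher, and rows of TK1, mcm4 and dhfr at -1.37, -1.32 and -1.28. Oxidative phosphorylation genes had a median of -0.45 (percentile 0.00 with either matching), with 6 of 195 at least 2-fold lower and 4 higher. The share at least 2-fold lower was not above that of all genes (1264 of 28711), while 167 of the 195 were below 0. On library totals the median was -0.11. The hypoxia-linked subunit COX4I2 was 3.58-fold higher. Erythroid markers had a median of -0.73 (percentile 0.00) and hbb was at -0.97 in its most abundant row. Muscle markers had a median of -0.80 (percentile 0.00).

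Ribosomal proteins had a median of -0.48, at percentile 0.00 among equally abundant genes and 100 among genes also matched on length, and of -0.11 (percentile 85.7) with the length trend removed. The antioxidant list had a median of -0.29 (percentiles 0.22 and 5.98), and 0.04 on library totals. Liver and pancreas markers had a median of -0.37 (percentiles 1.10 and 5.58) with apoa2 at 229 and 294 counts. The glucocorticoid list had a median of 0.21 (percentiles 98.3 and 96.3). The lists of glycolysis (median -0.07), chaperones (-0.02), endoplasmic reticulum stress (0.03), apoptosis (-0.01), inflammation (0.12), interferon (-0.10), complement (0.30), antigen presentation (-0.12), steroid synthesis (0.12), clock (0.23) and lipid storage (-0.04) lay inside the central 95% of random lists. The markers of thrombocytes (0.11), neutrophils (-0.22), chromaffin cells (0.06) and kidney tubule (0.05) did too. Each of these medians below 0 was above 0 on library totals. The clock gene nr1d2b was 2.64-fold higher, and star was 1.55-fold higher at 4536 counts.

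ALOXE3, a lipoxygenase family gene, was at 2694 counts in the control, 213 in moderate and 271 in severe hypoxia, a log2 ratio of -3.60 for severe hypoxia and -2.06 over its 9 rows. A COL10A1 row was at -6.35, and its 3 rows together at -4.36. TRIM62 was at 233 counts in the control and 0 in severe hypoxia, at least 284-fold lower in that row, and at -0.46 over its 5 rows. EEF1B2, a translation elongation factor subunit, was at 19.1, 6.28 and 1297 counts in the 3 groups in 1 row, and both rows together were at -0.50. Of the 28711 genes, 3934 were at least 2-fold higher and 1264 lower, so 75.7% were higher. On library totals the split was 5868 and 599, or 90.7% higher.

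**Figure D2:**
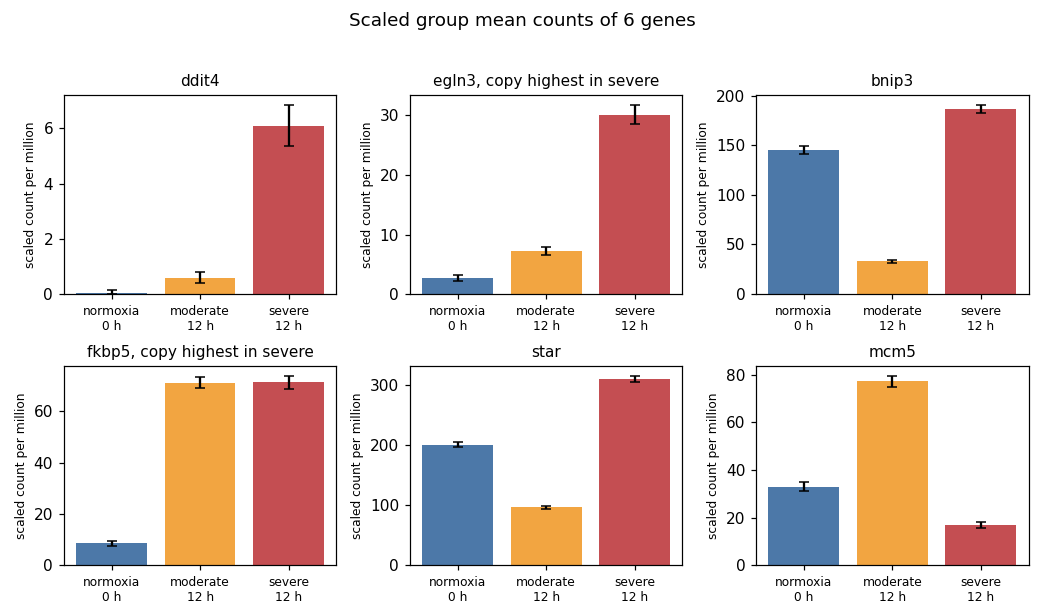
Group mean scaled counts (y axes, from 0) for 6 genes in the control, moderate and severe groups (x axes). Bars are the authors' group means after scaling and error bars are exact 95% Poisson intervals, which cover counting error only. The deposited counts of egln3 were 31.7, 140 and 441, and those of mcm5 were 397, 1505 and 248.

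Severe was set against moderate hypoxia to ask how the oxygen levels differ at the same sampling time. HIF targets, autophagy, interferon and complement genes, chromaffin and red blood cell markers, and liver and muscle markers were higher in severe hypoxia. On scaled counts, these lists except HIF targets lay further from the control in moderate than in severe hypoxia. Medians against the control, moderate before severe, were -0.74 and -0.10 for interferon and -1.10 and 0.30 for complement. They were -0.66 and 0.06 for chromaffin, -1.11 and -0.73 for erythroid and -3.22 and -0.80 for muscle markers. On library totals this could differ, with chromaffin markers at 0.03 and 0.40. DNA replication and endoplasmic reticulum stress genes were lower. The mitophagy receptor gene bnip3 was at 643 and 2735 counts, 5.64-fold higher (counting interval 5.37 to 5.93), in 1 of its 5 rows, and at a log2 ratio of 1.65 over all of them. The star gene was at 1875 and 4536 counts, 3.21-fold higher (counting interval 3.11 to 3.31).

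The HIF list had a median of 0.58 (percentile 100), with 22 of 64 members at least 2-fold higher and 2 lower, among them a ddit4 row (10.4-fold; log2 ratio 1.01 over its 3 rows) and the egln3 copies (4.17-fold and 3.23-fold). Autophagy genes had a median of 0.46 (percentile 100), with ATG12 and atg101 3.24-fold and 3.00-fold higher. Interferon genes had a median of 0.52 (percentile 100), with rsad2, which encodes viperin, at 6.67 and 66.3 counts. Complement genes had a median of 0.93 (percentile 100), with 17 of 35 at least 2-fold higher and haptoglobin HP at 5.25. Steroid synthesis genes had a median of 0.51 (percentile 99.7; 97.1 with the length trend removed, inside the central 95%), and 4 of 25 were at least 2-fold higher and 4 lower. The chromaffin list had 7 of 7 members above 0 with a median of 0.73 (percentile 98.8; 97.0 on FPKM with a pseudocount of 1), and pnmt, which makes adrenaline, was 2.45-fold higher. Erythroid markers had a median of 0.48 (percentile 99.0), muscle markers 2.26 and liver markers 1.73, the last pair at percentile 100.

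DNA replication genes had a median of -1.10 (percentile 0.00), with 32 of 58 at least 2-fold lower and 0 higher. Rows of CDC6, mcm5 and mcm4 were at -2.61, -2.19 and -2.02, and the symbols over all rows at -1.42, -2.10 and -1.91. Endoplasmic reticulum stress genes had a median of -0.47 (percentile 0.00), with a dnajb11 row at -2.22 and hspa5, the chaperone BiP, at -1.97. The inflammatory list had a median of -0.21 (percentile 1.30), and of -0.10 (percentile 11.3) with the length trend removed. An ldlr row, the low-density lipoprotein receptor, was at -3.34. The mmp9 row was at -2.21.

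Ribosomal proteins had a median of 1.01 and oxidative phosphorylation genes of 0.41, both at percentile 100 among equally abundant genes, and at 63.9 and 25.4 among genes also matched on length. With the length trend removed, the oxidative phosphorylation median was at -0.08 (percentile 0.19), so the list passed from above the central 95% of random lists to below it, and the ribosomal protein median of 0.31 lay above it. The antioxidant (median 0.39), apoptosis (0.24) and lipid storage (-0.24) lists were likewise outside the central 95% of random lists only without length matching, and the apoptosis median was -0.11 on library totals. T and NK cell markers (median -0.29) were at percentile 2.52, and at 0.23 with length matching. The lists of glycolysis (0.17), chaperones (0.13), antigen presentation (0.20), glucocorticoid response (0.12) and clock genes (-0.08) lay inside, as did markers of thrombocytes (0.09), neutrophils (-0.02), macrophages (0.25), B cells (0.06), endothelium (0.07) and kidney tubule (-0.26). On library totals the medians above 0 among these were below 0. Of single genes, EIF3B and timm10 were at least 285-fold and 158-fold lower in severe hypoxia, and timm10 was at -0.98 over both its rows. Of 28711 genes, 2592 were at least 2-fold higher and 3012 lower, so 46.3% were higher. On library totals the split was 1259 and 5599, or 18.4% higher.

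The 2 hypoxia groups were compared through their ratios to the shared control. Across genes, which are not independent replicates, the log2 ratios had a Pearson r of 0.75 and a Spearman rho of 0.69. Simulated groups with no effect gave an r of 0.53, 0.51 and 0.50 at assumed coefficients of variation between animals of 0.2, 0.4 and 0.8, because the control is shared. The covariance was 0.91, against 0.05, 0.14 and 0.54 in those simulations. At least 2-fold higher in both were 3326 genes, lower in both 775, and 63 went in opposite directions. Independent lists of these sizes would share 786 and 178 genes. The simulations gave 31, 234 and 2161 genes higher in both, and 5, 113 and 1481 lower in both, the last more than observed. The control could not be split, so part of the excess may come from it, and the variation between animals is unknown.

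**Figure D3:**
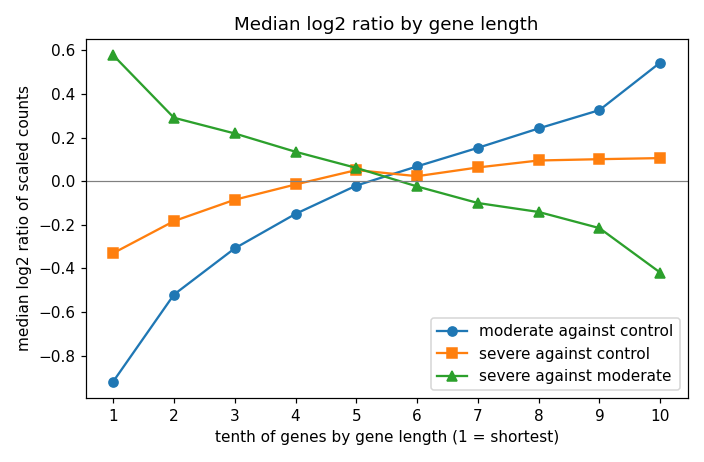
Median log2 ratio of scaled counts (y axis) in 10 equal parts of the genes ordered by gene length (x axis, shortest first), 1 line per comparison. For moderate against control the median ran from -0.92 in the shortest genes to 0.54 in the longest, and for severe against moderate from 0.58 to -0.42.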

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

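No paired analysis was possible because the file holds 1 value per group, so the replicate numbers of the labels attach to no column. For the same reason the planned Wald test, fit on 6 libraries, estimated-correlation and self-contained list tests, stricter adjusted p, filter per library and leaving out of single libraries were not run. Library totals, median-of-ratios size factors and the absence of a filter were planned; all other settings were chosen after seeing the data. Median-of-ratios size factors kept all 9 counts, overlaps and the correlation within 1.5 times, and kept the sign of 359 of 359 single gene ratios. Of all 359, 351 kept their sign under library totals and on either FPKM scale, and 356 after removal of the length trend. The 310 ratios of at least 2-fold all kept their sign under those settings. For library totals that was fixed in advance, since they move all ratios of a comparison equally, by less than 2-fold. The FPKM values are scaled by library size too, and a pseudocount leaves a sign as it is. The FPKM scales are therefore no separate check of these signs. Of 96 list medians, 68 kept their sign on library totals, 67 on either FPKM scale and 80 after removal of the length trend; of the 52 outside the central 95% of random lists, 50, 49 and 51 did. After removal of the length trend, 78 of 96 stayed on the same side of those limits and 1 passed from above to below them. A scaling common to all genes cannot move the percentiles.

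On library totals the counts were 10899 higher and 1354 lower for moderate against control, 599 lower for severe against control, and 1259 higher and 5599 lower for severe against moderate, with 5229 higher and 304 lower in both. Totals without globin and mitochondrial genes gave 9112 and 1854, 750 lower, 1464 and 4876, and 401 lower in both. These shifts follow from the scale factor. Without a filter the counts were 7482 lower for moderate against control, 6177 higher and 3580 lower for severe against control, 5201 and 5053 for severe against moderate, and 1894 lower in both. With at least 50 counts, they were 3689 higher for moderate, 2260 and 622 for severe, 1601 and 1995 for severe against moderate, and 1993 and 385 in both, from fewer genes.

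At 1.5-fold there were 7472 genes lower in moderate, 6396 higher and 3773 lower in severe, 6044 and 6259 for severe against moderate, and 5201 and 2456 in both. At 4-fold there were 2567 and 841 in moderate, 1075 and 201 in severe, 457 and 408 for severe against moderate, and 916 and 114 in both. With FPKM + 1 there were 628 lower in moderate, 1110 and 131 in severe, 473 and 1862 for severe against moderate, and 911 and 87 in both. With FPKM + 0.1 there were 9726 and 1192 in moderate, 411 lower in severe, 1048 and 4625 for severe against moderate, and 235 lower in both. With the length trend removed, 2671 genes were lower in moderate.

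Among lists outside the central 95% of random lists, the sign of 4 medians turned. Oxidative phosphorylation in severe against moderate was at -0.083 with the length trend removed. Antioxidant genes in severe against control were at 0.044 on library totals, 0.023 with FPKM + 1 and 0.026 with FPKM + 0.1. Apoptosis genes in severe against moderate were at -0.106, -0.089 and -0.103 on those scales. Interferon genes in moderate against control were at 0.02 with FPKM + 1 and 0.013 with FPKM + 0.1. On library totals the turns follow from the scale factor, and the percentiles stayed at 0.22 for antioxidant and 98.2 for apoptosis genes. On the FPKM scales the median of all genes was 0.378 and 0.629 for moderate against control. Interferon genes stayed at percentile 0.00 on both. The FPKM values are scaled by library size too, so the turns of antioxidant and apoptosis genes on those scales go with the same factor. Interferon genes were at -0.736 on scaled counts and already at -0.047 on library totals, so most of their move goes with it as well. What remains on the FPKM scales, and the turn with the length trend removed, were not tested further. Depth limits genes near the minimum count, and the spread between fish, which is not held, limits all ratios.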

Other observations

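Of 109 first-listed KEGG pathways with at least 10 genes, 18 lay above and 15 below the central 95% of random lists in severe against control under both matchings. The numbers were 11 and 2 in moderate against control, and 4 and 15 in severe against moderate. In severe against control, those below included the proteasome (median log2 ratio -0.50, 108 genes) and porphyrin metabolism, which includes haem synthesis (-0.43, 29 genes). Ribosome biogenesis (-0.31, 89 genes) and the cell cycle (-0.27) were also below, with medians of 0.03 and 0.07 on library totals. Lysosome genes (0.12, 180 genes) and cell adhesion molecules (0.40, 150 genes) were higher. Some pathways lay above the limits in moderate and below them in severe hypoxia: aminoacyl-tRNA synthesis was at 0.23 in moderate and -0.25 in severe hypoxia against the control, the Fanconi anaemia DNA repair pathway at 0.30 and -0.33, and nucleocytoplasmic transport at 0.37 and -0.14, while on library totals their medians in severe hypoxia were above 0, at 0.09, 0.01 and 0.20. Ferroptosis genes were at -0.86 in moderate hypoxia, and mitophagy genes at 0.43 in severe against moderate. HIF targets ordered control, moderate, severe made up 17 of 64 list members (26.6%), against 10.2% in random lists matched on abundance and length (percentile 100), so the length trend does not account for that order.

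The tests of scaling and of red blood cells, the nearest-gene matching, which replaced a coarser one, and the use of a binomial p for genes near 0 were chosen after the results were seen. The first pattern weighed is the lower level of ribosomal protein and oxidative phosphorylation transcripts in moderate hypoxia. Against the genes nearest in abundance and length, ribosomal proteins lay at percentile 92.2 (-1.51 against -1.58) and oxidative phosphorylation at 0.43 (-0.92 against -0.79), but with the length trend removed it was the reverse, at percentiles 0.26 (-0.42) and 88.6 (-0.06). How much of both goes with the gene length trend thus depends on how length is allowed for. Ribosomal proteins and globins were not kept out of the draws for oxidative phosphorylation, nor globins out of those for ribosomal proteins. Short genes drawn in this way may share the decrease for another reason, so the matching cannot show that length is its cause. Scaling is argued against for ribosomal proteins by a median of -0.82 on library totals, and stays open for oxidative phosphorylation at -0.23. Fewer red blood cells cannot be told apart: the ribosomal proteins lay 1.14 above the globins on the log2 scale but below the erythroid median of -1.11, and hypoxia, sampling time and RNA handling stay open and untested.

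The second pattern is the lower level of liver and muscle transcripts in moderate hypoxia. Gene length does not account for it, since the liver list (14 members, 12 at least 2-fold lower) lay at percentile 0.00 among its nearest genes. Of 27 hepatocyte genes outside that list, the median was -2.26 in moderate and -0.105 in severe hypoxia, as carry-over of liver tissue in the dissections of the other groups would give. A candidate explanation is thus tissue next to the organ in some control and severe samples; AMBP, the most abundant of the 27, was at 2180, 2516 and 2760 counts and did not follow, and 12 of the 27 reached 10 counts in moderate hypoxia. A response of these genes to moderate hypoxia stays open, as no value per fish is held.

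The third pattern is 51 genes at 3 counts or fewer over 1 group and at 50 or more per library in another, 37 of them lowest in the control, 10 in moderate and 4 in severe hypoxia. Of the 34 whose symbol has other rows, those rows gained at least 50% of the missing counts for 11 genes and lost as many for 18 (two-sided exact binomial p = 0.265). Reads moved between copies with the same symbol cannot be told apart from other causes, because the IDs end after 8 characters and copies with other symbols are not matched.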
